A study of Sus scrofa with 43 samples.

How the data were processed

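The deposited files held read counts per Ensembl gene for each of the 43 libraries. Per the submitters' processing notes, the reads were trimmed with Trim Galore and aligned with HISAT2 to the pig genome Sscrofa11.1. They were then counted with HTSeq and compared with DESeq2, and no versions were stated. Per the labels' protocols, total RNA came from whole blood. The strand setting and the annotation release used in counting were not stated. No genome sequence was used here, so no gene positions are given. A library's group was read from its treatment tag, because the titles were running numbers. The replicate numbers used here follow the order of the records only. No paired analysis was possible because the labels do not say which libraries belong together.

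Each library listed 31907 gene IDs, of which 15029 had a symbol in the supplied table that pairs IDs with symbols. The HTSeq categories that name no gene were set aside before fitting. As a percentage of the counts assigned to genes, their median over the libraries was 78.4 for reads aligned to more than 1 place, 15.3 for ambiguous reads, 0.545 for low alignment quality, 0.352 for unaligned reads and 0.228 for reads outside any gene. Genes were kept by edgeR's filterByExpr with a minimum count of 10 and a minimum total of 15, which left 9428 IDs, 8322 of them with a symbol.

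Counts were scaled by TMM and fitted with edgeR 4.0.16 in R 4.3.3, with 1 mean per group and robust quasi-likelihood F tests, which are two-sided. The 5 comparisons were the effect of high glucose in infected and in uninfected pigs, the effect of infection at high and at standard glucose, and the interaction of both. All p-values were adjusted by Benjamini-Hochberg over the 9428 genes of a comparison, with a threshold of 0.05. DESeq2 1.42.0, limma 3.58.1 (voom with sample quality weights) and sva 3.50.0 (2 surrogate variables) served as alternatives. Levels of single samples are log2 CPM (counts scaled to a common library size) with a prior count of 2.

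A common dispersion was estimated for every pair of libraries from genes with a summed count of at least 40. Pairs below 0.02 were treated as repeats, the linked libraries were summed into 1 sample, and all 5 comparisons were fitted again on the sums. This second fit was added after the data were seen, and its counts stand beside the library counts. Means and standard deviations (SD) are over the summed samples.

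There were 31 gene lists, written from general knowledge before the data were examined, as were the 5 comparisons, the threshold, the rule for naming genes and most alternatives. Lists were tested with limma's camera at a preset correlation of 0.01, with camera at a correlation estimated from the data, and with fry. Camera asks whether a list's genes differ from the other genes. Fry asks whether they move, on balance, one way, and compares them with no other genes. The list p-values were adjusted over the 31 lists. Each list's mean log2 CPM per summed sample was also compared by a two-sided test, exact where a group held fewer than 10 samples and otherwise with 100000 random permutations. Scores of the erythroid, mature neutrophil and T cell lists served together as 3 covariates for cell composition.

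Genes were named by rule. They were the 8 largest rises and the 8 largest falls among genes with a symbol, an adjusted p below 0.05 and a mean log2 CPM of at least 3. Up to 4 members per described list with the smallest p were added, and a fixed panel of inflammatory, glycolytic and cell type genes where tested. Where fewer than 4 genes passed, the 4 with the smallest p were named. Further list members stand only for values that did not pass.

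Where the control libraries held 1 to 3 counts of a gene in all, and for CXCL8 and CXCL10 also at 5 counts, a ratio of pooled counts is given with a 95% counting interval, and where they held 0 the ratio is a lower bound against a floor of 3 counts over the group. These intervals and floors cover counting error only. Sample labels were shuffled up to 100 times with both fits, and up to 60 times with the composition covariates.

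The steps were tested on simulated data with 200 changed genes among 9428 and with repeats built in. With the infected group sizes, 16.0% of the calls were false at a log2 fold change of 1 when repeats counted separately, and 4.39% were false when they were summed. Recovery was 65.5% and 54.5% of the changed genes. With the group sizes of infection at standard glucose and the same fold change, 26.9% of the calls were false with repeats separate and 6.67% summed, and recovery was 24.5% and only 7%. At a log2 fold change of 2 recovery there was 84.5% and 69%, so smaller effects against 3 control samples were mostly missed. With no gene changed, the mean number of calls over 5 simulations was 4.4 and 0.6. The simulated genes varied independently of each other, which real genes do not. With the real data and shuffled glucose labels, the mean was 81.6 calls with sets kept together but libraries separate (highest 1542). Summed, it was 6.44 (highest 333), so the simulated error rates need not hold for these data.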

Results

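RNA was sequenced from the whole blood of preterm pigs (Sus scrofa). The animals either received Staphylococcus epidermidis, a skin bacterium that can enter the blood of preterm newborns, or served as uninfected controls, and they were fed intravenously with a high or a standard glucose supply. The 43 libraries comprised 18 from infected pigs at high glucose (SE-High), 17 from infected pigs at standard glucose (SE-Std), 4 from controls at high glucose (CON-High) and 4 from controls at standard glucose (CON-Std). The series text also describes inhibition of glycolysis, which no sample label names and which was not analysed here. Counts assigned to genes ranged from 2360400 to 4294375 per library (median 2994867), and 8803 to 13813 genes were detected per library. An ID without a symbol, ENSSSCG00000007978, held 25.3% of all gene counts. It was followed by FTL, the light chain of the iron store ferritin, with 9.10%, TPT1 with 6.13%, the beta-globin gene HBB with 4.12% and ALAS2, an enzyme of red-cell haem synthesis, with 3.10%. Haemoglobin genes have near-identical copies, so the HBB value is uncertain.

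Among the 903 pairs of libraries, 10 pairs were far more alike than all others, with a biological coefficient of variation of 4.88 to 9.90%. The next pair stood at 19.3% and the median of the other pairs was 42.5%. The pairs from 19.3 to 21.9% also all lay within a group, so further related samples may remain. All 10 pairs lay within a group and linked 14 libraries into 6 sets, and in each of the 6 sets the Y-linked gene EIF1AY was either present in all libraries or absent from all. Counting each set as 1 sample left 35 samples, of which 12 were SE-High, 17 SE-Std, 3 CON-High and 3 CON-Std. The labels do not say that the libraries came from separate animals, so p-values measure the spread between these samples. Counts of genes are therefore given over the 43 libraries and again over the 35 samples with repeats summed. List members named for infection are given for the summed samples, pooled ratios for the libraries, and a single named gene is said to rise or fall only where both fits passed.

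**Figure D1:**
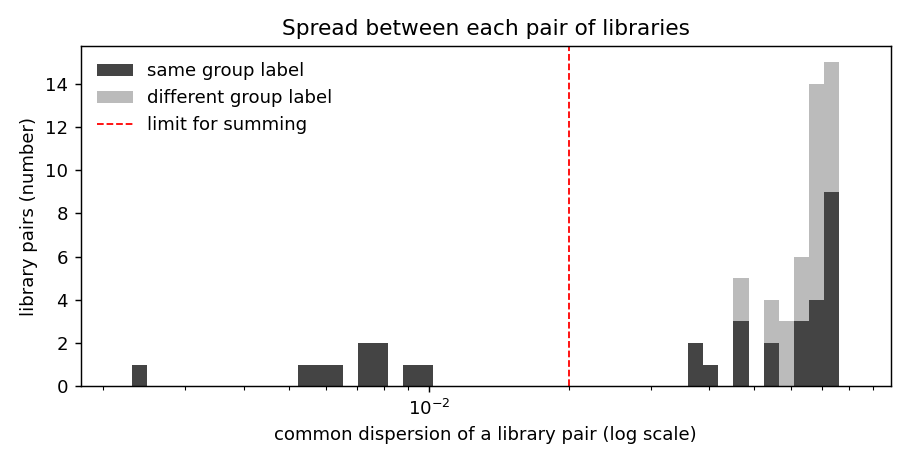
Number of library pairs (y axis) by the common dispersion of the pair (x axis, log scale, low end shown), with pairs of the same group dark, pairs of different groups light and the limit of 0.02 dashed. The 10 pairs below the limit reach at most 0.00980, and the next pair stands at 0.0371.

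The first comparison asked how blood expression changed with infection at high glucose. ACOD1 (ENSSSCG00000009469), which makes the antimicrobial metabolite itaconate in activated myeloid cells, averaged 5.02 ± 0.69 log2 CPM (SD, n = 12) in SE-High against -0.97 ± 0.21 (n = 3) in CON-High. With 1 count in the CON-High libraries, its pooled ratio was 678 with a counting interval of 122 to 26795. MMP8, a collagenase of neutrophil granules, averaged 7.41 ± 0.89 against 0.00 ± 0.96 log2 CPM, a log2 fold change of 7.81 over libraries and 8.10 ± 0.96 (standard error) over summed samples (adjusted p = 2.8e-07). FGL2, a prothrombin-cleaving enzyme of macrophages and T cells, fell from 5.90 ± 0.13 to 2.78 ± 1.05 log2 CPM, a log2 fold change of -3.11 over libraries and -2.91 ± 0.53 summed (adjusted p = 0.000452).

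Other large rises at high glucose were TNFAIP6, a hyaluronan-binding protein induced by TNF, with log2 fold changes of 6.97 over libraries and 7.19 summed, the membrane protein gene MS4A8 with 6.56 and 6.88, and the RNA-degrading interferon target ISG20 with 5.88 and 6.25. The chemokine genes CXCL8, CCL4 and CXCL10 each had 3 counts in the CON-High libraries. Their pooled ratios were 183 (62.5 to 889) for CXCL8, which attracts neutrophils, 89.6 (30.5 to 435) for CCL4 and 66.3 (22.5 to 322) for CXCL10. The falls included the metalloprotease gene ADAM19 (-2.72 and -2.73), the sorting receptor SORL1 (-2.33 and -2.42), PLEKHG3 (-2.03 and -1.96), the interleukin-6 receptor IL6R (-1.85 and -1.72), the kinase SGK1 (-1.84 and -1.67) and SDS (-1.68 and -1.57). TGFBI passed over libraries at -2.07 but not summed, at -2.03 with an adjusted p of 0.0518. The expression limit for named genes leaves out genes that were low in the infected samples, so larger falls than these exist. VNN1, chosen after its values were seen, stood at 3.31 to 4.49 log2 CPM in the control samples of both glucose supplies. In the infected samples it stood at 0.794 or lower. Of the fixed panel, S100A8 (4.54 and 4.89), HK2 (3.71 and 3.58), IL10 (3.22 and 3.17), TLR2 (1.91 and 2.03) and HBB (1.91 and 1.98) rose, and CD3E fell (-0.996 and -0.91). The log2 fold changes of LDHA (0.63 and 0.58), PFKFB3 (-0.026 and -0.072) and the monocyte receptor CD14 (0.21 and 0.40) did not pass. CD14 stood at -1.03 with the 3 composition covariates, which hold no monocyte score (adjusted p = 0.00621).

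The type I interferon list held the most genes that rose at high glucose. Of 32 type I interferon genes, 26 rose over libraries (30 adjusted over the list alone) and 24 summed (30 adjusted over the list alone), with a median log2 fold change of 2.53 and 2.81. An example was the antiviral GTPase MX1 (4.84 ± 1.03 summed). The list passed camera (adjusted p = 2.4e-18), with an adjusted p = 0.114 with an estimated correlation. Of 17 interferon gamma and antigen processing genes, 11 rose over libraries (13 adjusted over the list alone) and 10 summed (15 alone), including the adhesion gene ICAM1 (3.22 ± 0.43 summed) and the feedback inhibitor SOCS1 (2.36 summed). Their camera call was lost at an adjusted p = 0.0923 with an estimated correlation. MHC class II genes went the other way, with 6 of 8 falling over libraries and 5 summed (6 alone in both fits), such as SLA-DMB (-1.65 ± 0.35 summed). The protease CTSS of the same list rose (1.01 summed), and this list had an adjusted p = 0.114 with an estimated correlation. SLA genes have near-identical copies, so their values are uncertain.

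Among inflammatory genes at high glucose, 8 of 13 cytokines and chemokines rose and 1 fell over libraries (9 and 1 adjusted over the list alone), and 7 rose summed (8 up and 1 down alone), including CSF1 (3.52 summed). Of 33 Toll-like receptor and NF-kB genes, 10 rose and 1 fell over libraries (11 and 2 adjusted over the list alone) and 7 rose summed (10 alone), among them RELB (2.48 ± 0.36 summed) and the inhibitor NFKBIA (3.47 summed). The anti-inflammatory list had 12 of 19 genes rising in both fits (14 and 13 alone), with ANXA1 (2.06 summed). IL1RAP (4.21 summed) was counted because the list holds it, and whether it acts against inflammation here was not tested. Of 11 neutrophil granule genes 7 rose in both fits (7 alone), including S100A12 (4.68 summed) and LTF (3.64 summed). Of 6 acute phase genes 4 rose over libraries (5 alone) and 3 summed (5 alone), including the iron-binding LCN2 (5.64 ± 1.05 summed). These lists passed camera. With an estimated correlation the adjusted p was 0.0756 for cytokines, 0.158 for NF-kB genes, 0.0709 for the anti-inflammatory list, 0.0756 for granule genes and 0.0459 for acute phase genes (0.0727 summed).

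Markers of several blood cell types moved in the same comparison. T cell markers fell in 11 of 20 cases over libraries (14 adjusted over the list alone) and 8 summed (10 alone), with CD6 (-1.12 ± 0.24 summed), CD5 (-1.02), LCK (-0.92) and LEF1 (-1.04). B cell markers fell in 5 of 14 cases (5 alone) and 3 summed (5 alone), including CD79A (-1.10 summed). Erythroid markers rose in 11 of 20 cases (15 alone) and 7 summed (13 alone), including RHCE (1.81 ± 0.45 summed) and ANK1 (2.002 summed), beside 13 of 22 cell cycle genes (20 alone) and 8 summed (18 alone), such as CCNB1 (2.28 summed). Monocyte markers rose in 3 of 8 cases in both fits (4 and 3 alone), including the scavenger receptor CD163 (2.91 summed) and VCAN (2.07 summed). Their mean score was higher by 1.02 log2 units in SE-High, with 12 of 12 samples above all controls (exact permutation test, adjusted p = 0.00681). With an estimated correlation, the adjusted p was 0.114 for T cell, 0.420 for B cell, 0.355 for erythroid, 0.147 for monocyte and 0.114 for cell cycle genes. With 3 composition covariates the erythroid list reversed its direction (camera adjusted p = 0.645), as did the nuclear oxidative phosphorylation list (0.0549). The erythroid score is itself 1 of these covariates, so the sign left for that list carries no information. Of 16 glycolysis genes, HK2 and HK3 (2.28 ± 0.51 summed), which phosphorylate glucose, rose in both fits (2 alone). The list median was 0.26 over libraries (camera adjusted p = 0.0229, and 0.358 with an estimated correlation). Of 18 immediate early and heat shock genes 9 rose over libraries and 8 summed (11 up and 1 down alone, then 9 up), including ATF3 (2.52 summed) and IER3 (3.95 summed), with an adjusted p = 0.0756 with an estimated correlation.

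For infection at high glucose 865 genes were higher and 530 lower with infection over libraries, 1395 in all, and 551 were higher and 323 lower summed, 874 in all. Voom with quality weights gave 2566 over libraries. For infection at high glucose, repeats summed, voom gave 2508 and DESeq2 1343. The counts depended on single control libraries. Without CON-High replicate 3, 4 or 1, they were 691, 733 and 908 over libraries and 248, 239 and 476 summed, and 177 genes passed when a wider limit merged further libraries. Camera called 17 of the 31 lists over libraries and 17 summed, fry 16 and 15, and camera with an estimated correlation 1, the acute phase list, and 0. Exact permutation tests of the summed list scores called 14.

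The same question was asked at standard glucose, where ACOD1 again had the largest fitted rise. The pooled ratio of ACOD1 in SE-Std against CON-Std, with 1 control count, was 865 with an interval of 155 to 34188. ALPL, a phosphatase of mature neutrophils, had 0 counts in the CON-Std libraries and was at least 78.5-fold higher in SE-Std. ISG20 rose by a log2 fold change of 7.62 over libraries and 7.61 ± 1.27 summed (adjusted p = 0.000173). ADAM19 fell by -3.02 over libraries and -3.09 ± 0.33 summed (adjusted p = 2.1e-08). IL6R fell by -1.99 over libraries and -2.002 ± 0.25 summed (adjusted p = 6.2e-07).

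Further rises at standard glucose were MS4A8 (7.12 and 7.20) and a set of chemokine genes with few control counts. Their pooled ratios were 306 (54.9 to 12117) for CCL4 and 328 (58.7 to 12966) for CXCL2, each with 1 control count. They were 109 (46.7 to 337) for CXCL10 and 100 (42.8 to 309) for CXCL8, each with 5. Falls included SORL1 (-2.21 and -2.26), RGS2, which dampens G-protein signals (-2.06 and -2.16), FGL2 (-2.02 and -2.09), PRKX (-1.70 and -1.60), LGALS3 (-1.54 and -1.48) and MYLIP (-1.50 and -1.55). S100A8 (4.28 and 4.21), HK2 (3.11 and 3.20), IL10 (3.11 and 3.10) and TLR2 (1.76 and 1.75) rose. LDHA (1.25, adjusted p = 0.0281) and CD3E (-0.75, adjusted p = 0.0302) passed over libraries but not summed (adjusted p = 0.0952 and 0.0718). HBB (0.996 and 0.97), CD14 (0.20 and 0.11) and PFKFB3 (0.0035 and -0.025) did not pass. CD14 stood at -1.22 with the composition covariates (adjusted p = 0.00117).

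Of the 32 type I interferon genes 29 rose at standard glucose over libraries (31 adjusted over the list alone) and 27 summed (31 alone), with medians of 3.02 and 3.14, including MX1 (5.45 ± 1.07 summed) and BST2, which tethers viruses to the cell (4.14 summed). The list had an adjusted p = 0.0578 with an estimated correlation. Of 17 interferon gamma genes 14 rose (15 alone) and 13 summed (15 alone), including ICAM1 (3.41 summed) and WARS1 (1.95 summed). Of 13 cytokines and chemokines 9 rose and 1 fell over libraries, and 7 rose and 1 fell summed (9 up and 1 down alone in both fits), with CSF1 at 4.48 summed. Of 19 anti-inflammatory genes 8 rose in both fits (13 up and 1 down alone, then 12 and 1), including the checkpoint gene HAVCR2 (4.46 summed). Acute phase genes rose in 3 of 6 cases in both fits (4 and 3 alone), with LCN2 at 5.602 summed, and neutrophil granule genes in 7 of 11 cases (9 alone), with LTF at 4.18 summed. The calls of these last lists held with an estimated correlation. The adjusted p was 0.0302 for interferon gamma, anti-inflammatory and acute phase genes and 0.0310 for cytokines and granule genes, and summed the granule list alone was lost (0.0530).

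T cell markers fell in 9 of 20 cases at standard glucose (11 adjusted over the list alone) and 3 summed (11 alone), with CD5 (-1.06 summed), LCK (-0.82) and CD6 (-0.75), and B cell markers in 6 of 14 cases (7 alone) and 3 summed (3 alone), with CD79B (-0.996 summed). With an estimated correlation their adjusted p was 0.136 and 0.227. Monocyte markers rose in 3 of 8 cases in both fits (3 alone), including CD163 (2.90 summed) and VCAN (1.86 summed), with an adjusted p = 0.0601 with an estimated correlation. Their mean score was higher by 1.34 in SE-Std, with 14 of 17 samples above all controls (exact permutation test, adjusted p = 0.00989). No erythroid marker of 20 passed (median 0.47, camera adjusted p = 0.193). Of 16 glycolysis genes 5 rose over libraries (8 alone) and 2 summed (6 alone), namely HK2 and HK3 (2.55 ± 0.51 summed), while ENO1 passed over libraries at 0.94 and not summed at 0.86 (adjusted p = 0.092). The list median was 0.65 over libraries (camera adjusted p = 6.8e-05, and 0.0715 with an estimated correlation). Of 16 cholesterol synthesis genes 4 rose (4 alone) and 3 summed (4 alone), with an adjusted p = 0.227 with an estimated correlation. Of 14 complement and coagulation genes 6 rose (10 alone) and 5 summed (6 alone), including C3 (2.47 ± 0.51 summed), with an adjusted p = 0.0847 with an estimated correlation. Of 18 immediate early and heat shock genes 9 rose over libraries and 6 summed (9 alone in both fits), with HSP70.2 at 3.26 summed, a gene with near-identical copies and so an uncertain value.

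For infection at standard glucose 728 genes were higher and 363 lower over libraries, 1091 in all, and summed 475 were higher and 192 lower, 667 in all. Voom gave 2742 over libraries. For infection at standard glucose, repeats summed, it gave 1588. Without CON-Std replicate 2, 1 or 4 the library count was 597, 623 and 695, and summed it was 260 without replicate 1 and 268 without replicate 4. Camera called 18 of 31 lists over libraries and 17 summed, fry 17 and 15, and camera with an estimated correlation 5 and 4. Exact permutation tests of the summed list scores called 13.

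The infection comparisons shared no libraries, so their overlap could be read directly. Their log2 fold changes correlated across the 9428 genes with r = 0.778 over libraries and 0.780 summed, where genes are not independent replicates. Both comparisons called 450 genes upward, where 66.8 would be expected by chance, and 247 downward, where 20.4 would. Summed, 307 and 125 genes were shared, with 27.8 and 6.58 expected. ADGRB1 passed in opposite directions over libraries and in neither comparison summed (adjusted p = 0.0502 and 0.0508). Of the 1109 genes called in either comparison summed, 99.2% had the same sign in both.

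**Figure D2:**
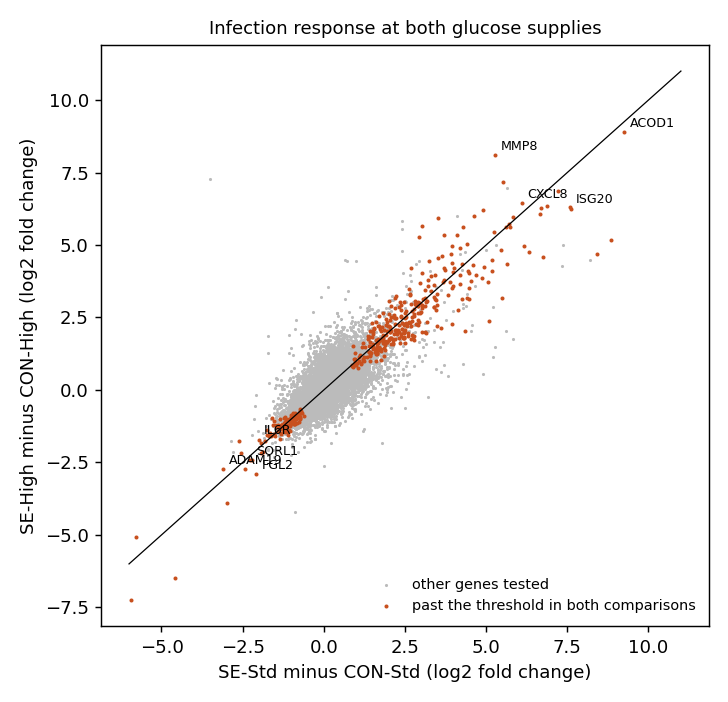
Log2 fold change with infection at standard glucose (x axis) and at high glucose (y axis) for each of 9428 genes, summed samples, with the 432 genes past the threshold in both comparisons in orange. The correlation across genes is 0.780, and ACOD1 and MMP8 lie among the largest rises while ADAM19 and SORL1 lie among the falls.

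The central comparison asked how a high glucose supply altered blood expression in infected pigs. ICAM5 (ENSSSCG00000013653), a member of the intercellular adhesion family best known from neurons, rose 3.13-fold, from 2.17 ± 0.80 log2 CPM (SD, n = 17) in SE-Std to 3.74 ± 0.78 (n = 12) in SE-High. Its log2 fold change was 1.68 over libraries and 1.65 ± 0.28 (standard error) summed (adjusted p = 0.00605). P2RY14 (ENSSSCG00000011712), the receptor for UDP-glucose and related nucleotide sugars on blood cells, fell by a log2 fold change of -2.24 in both fits (adjusted p = 0.0123 summed). P2RY14 lay below the expression limit for named genes, with a mean log2 CPM of 1.57, and was chosen after its values were seen. With infection at standard glucose P2RY14 rose (3.71 over libraries and 3.58 summed), while at high glucose its 1.42 and 1.47 did not pass, and the interaction of -2.29 over libraries (adjusted p = 0.999) and -2.11 summed did not pass either. ICAM5 and P2RY14 passed in all 29 fits that left out 1 infected sample, with adjusted p of at most 0.0291 and 0.0395. When a wider limit merged further libraries, only 1 gene passed, so these calls did not both hold.

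Several chaperone genes were higher at high glucose, and they passed over libraries but not after summing. HSPH1, a co-chaperone that recharges HSP70, averaged 7.34 ± 0.85 log2 CPM in SE-High and 5.72 ± 1.37 in SE-Std, with log2 fold changes of 1.33 over libraries (adjusted p = 0.0414) and 1.27 ± 0.39 summed (adjusted p = 0.224). BAG3, which couples HSP70 to protein clearance, had 1.16 and 1.13 ± 0.26 (adjusted p = 0.00647 and 0.0750). The HSP90 co-chaperone gene PTGES3 had 1.02 and 0.95 ± 0.21 (adjusted p = 0.00240 and 0.0643). Of the 18 immediate early and heat shock genes, HSPA1L (2.08 and 2.17), HSPH1 and DNAJA1 (0.70 and 0.71) passed over libraries (5 up and 3 down adjusted over the list alone) and 0 summed by edgeR (4 up alone), and HSP70.2 had 1.29 and 1.37 (adjusted p = 0.0631 and 0.224). HSPA1L and HSP70.2 have near-identical copies, so their split is uncertain. HSPA1L was also low, at 1.61 ± 1.25 log2 CPM in SE-High and -0.099 ± 1.03 in SE-Std, so its fold change rests on few counts. The list passed camera (adjusted p = 0.00918 over libraries and 0.00386 summed), with 0.407 and 0.355 with an estimated correlation. BAD (1.55 and 1.30), PORCN (1.09 and 0.89), PAIP2 (1.04 and 0.74) and COL16A1 (0.998 and 0.95) followed.

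Interferon targets were lower at high glucose, again past the threshold over libraries but not after summing. CXCL10 had log2 fold changes of -1.77 over libraries and -1.52 ± 0.52 summed (adjusted p = 0.0414 and 0.340). DDX60, a helicase that aids viral RNA sensing, had -1.64 and -1.49 ± 0.38 (adjusted p = 0.00720 and 0.124), with 3.49 ± 1.38 log2 CPM in SE-Std and 2.42 ± 0.64 in SE-High. GBP1 (-1.46 and -1.23), EPSTI1 (-1.28 and -1.02), the checkpoint ligand CD274 (-1.26 and -1.003) and WARS1 (-1.14 and -1.01) followed. Of 32 type I interferon genes 3 passed over libraries (26 adjusted over the list alone) and 0 summed by edgeR (1 alone), with medians of -0.91 and -0.69. Examples over libraries were TRIM25 (-0.93, and -0.79 summed with an adjusted p of 0.157) and BST2 (-1.24, and -1.04 summed with 0.307), while IFI44L (-0.92 and -0.71) passed in neither fit. The list passed camera (adjusted p = 1.5e-24 and 1.8e-18), with an adjusted p = 0.222 and 0.355 with an estimated correlation. Of 17 interferon gamma genes 6 passed over libraries (15 adjusted over the list alone) and 0 summed (8 alone), with medians of -0.70 and -0.50, including SOCS1 (-0.85 and -0.77) and CXCL9 (-2.56 and -2.36). This list kept its call with an estimated correlation over libraries (adjusted p = 0.0378) but not summed (0.156), and fry gave 0.000954 and 0.0636.

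Other genes that were lower over libraries included SELP, the platelet and endothelial adhesion molecule P-selectin (-1.50 and -1.40 ± 0.38, adjusted p = 0.0204 and 0.205), PPA1 (-1.26 and -1.16) and DAAM1 (-1.35 and -1.28). SELP was 1 of 12 platelet markers to pass over libraries (2 adjusted over the list alone), with 0 summed (1 alone), and ITGB3 (-0.86 and -0.81), GP6 (-0.71 and -0.66) and PPBP (-0.68 and -0.61) passed in neither fit. The platelet list passed camera (adjusted p = 4.4e-07 and 4.0e-06 summed), with an adjusted p = 0.342 and 0.355 with an estimated correlation. Of 19 anti-inflammatory genes 3 passed over libraries (5 alone) and 0 summed (4 alone), including HAVCR2 (-1.67 and -1.48). This list passed camera (adjusted p = 8.0e-05 and 0.000376), with an adjusted p = 0.222 and 0.355 with an estimated correlation. SOCS1 and CD274, given above as interferon targets, are members of this list too, so it is not separate from the interferon gamma list.

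Glycolysis, the pathway nearest to the treatment, had 0 of 16 genes past the threshold by edgeR in either fit, 0 also adjusted over the list alone, and 13 of the 16 were lower in SE-High over libraries. ENO1 (-0.44 and -0.41), HK3 (-0.57 and -0.41), PGK1 (-0.31 and -0.33) and PFKP (-0.39 and -0.36) did not pass, nor did HK2 (-0.059 and -0.20), LDHA (-0.36 and -0.45) or PFKFB3 (-0.13 and -0.14). HK2 changed sign to 0.067 with the composition covariates and 0.19 by voom. The list median was -0.23 over libraries and -0.25 summed, with a camera adjusted p of 0.0190 and 0.00857 and 0.407 and 0.378 with an estimated correlation. The inflammatory panel did not pass either. The log2 fold changes over libraries and summed were -0.43 and -0.69 for CXCL8, -0.49 and -0.69 for IL10, -0.32 and -0.20 for TLR2, 0.27 and 0.38 for CD14 and -0.22 and -0.067 for S100A8. S100A8 reversed to 0.22 over libraries with the composition covariates and to 0.088 by voom. CD3E was at -0.13 and -0.0029 and HBB at 0.57 and 0.51. Erythroid markers had a median of 0.44 over libraries and 0.25 summed (camera adjusted p = 0.000353 and 0.0296, and 0.651 and 0.753 with an estimated correlation). Mature neutrophil markers had -0.53 and -0.30 (0.0472 and 0.179, and 0.651 and 0.753 with an estimated correlation).

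**Figure D3:**
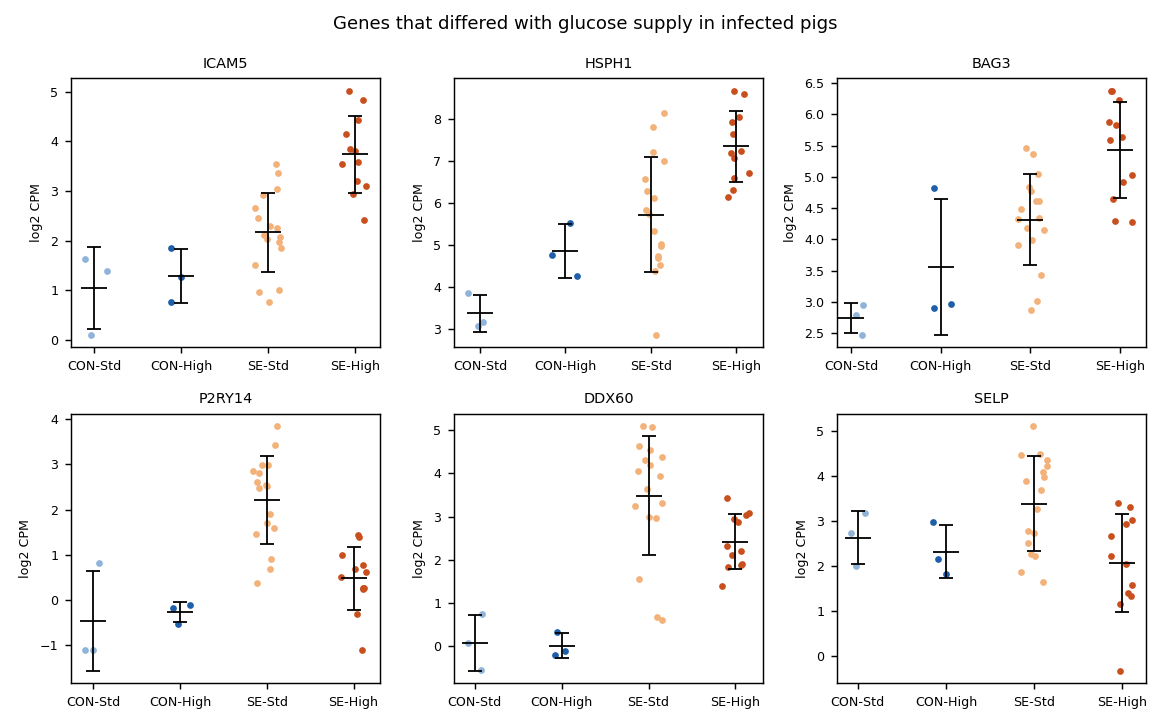
Log2 CPM (y axis) of ICAM5, HSPH1, BAG3, P2RY14, DDX60 and SELP in the summed samples of the 4 groups (points), with mean and SD as bars. ICAM5 averages 3.74 in SE-High against 2.17 in SE-Std, and DDX60 2.42 against 3.49, and among the 6 genes only ICAM5 and P2RY14 passed in both fits.

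In total 37 genes were higher and 87 lower in SE-High than in SE-Std over libraries, 124 in all, and 1299 had a nominal p below 0.05, where 471 would be expected. Shuffled labels that kept the sets together often gave as many. The number 1299 was reached by 23 of 100 splits, the real one included, and the median of the others was 880. Summing left 1 gene higher and 1 lower, 2 in all, with 822 at a nominal p below 0.05. All 124 genes kept their sign, which carries little weight because both fits use the same counts. Of 100 splits of the summed samples, the real one included, 15 reached 822 (highest other 2116). Over libraries DESeq2 gave 278 genes, voom 275, surrogate variables 343, the composition covariates 298 and a fit of the infected groups alone 60. Summed, DESeq2 gave 35 and voom 18. The summed count was 14, 12, 9 and 8 without SE-Std replicates 1, 3, 6 and 9, and 10, 13 and 6 without SE-High replicates 4, 9 and 14. Camera called 13 of 31 lists over libraries and 9 summed, fry 3 and 0, camera with an estimated correlation 1 and 0, and the permutation test of list scores 0.

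With the composition covariates added to the summed samples, a combination chosen after seeing the data, 24 genes were higher and 84 lower, 108 in all, and all 108 had the same sign without the covariates. HSPH1 (1.77 ± 0.33, adjusted p = 0.00691), BAG3 (1.18), PTGES3 (1.04), STIP1 (1.05) and DNAJB1 (1.105) were among those higher. DDX60 (-1.51, adjusted p = 0.0336), IFIT5 (-1.42), TMEM140 (-1.39), SELP (-1.37), KDR (-1.32) and DAAM1 (-1.31) were among those lower. Of the 108 genes 61 were also called over libraries. Neither these calls nor the shared signs are independent support, since the fits use the same counts. The covariates held no platelet score, and the platelet list, which includes SELP, stayed lower in this fit (median -0.64). The share of platelets was therefore not adjusted for.

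**Figure D4:**
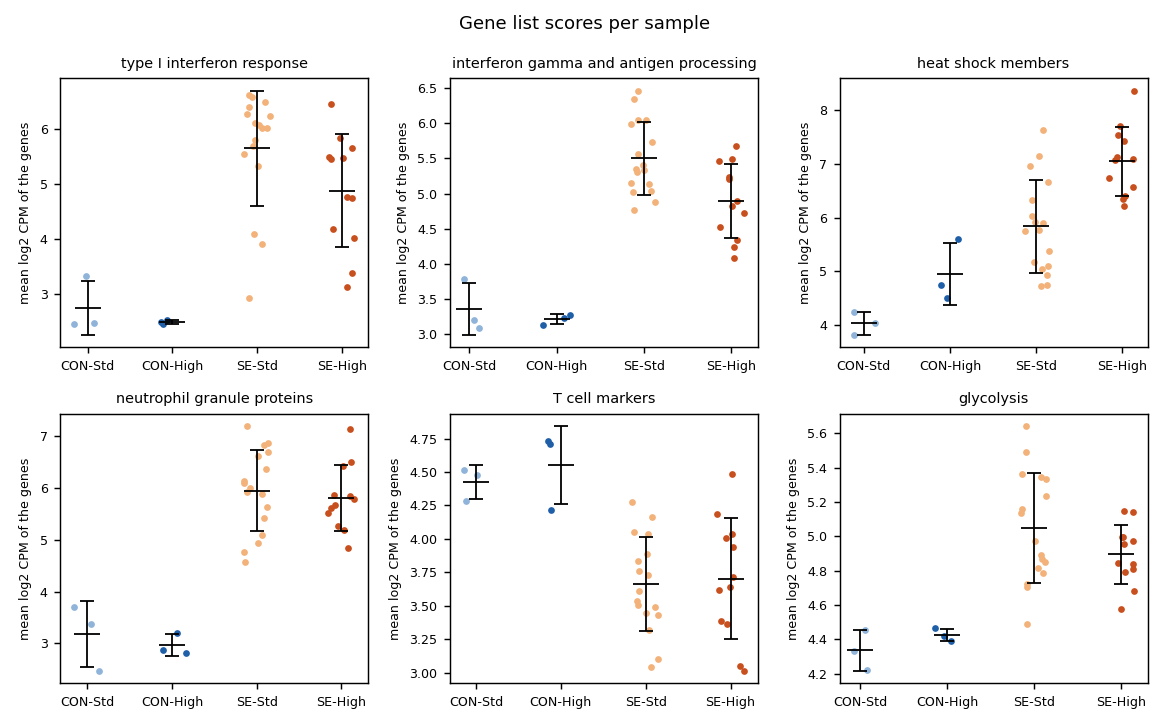
Mean log2 CPM (y axis) of the type I interferon, interferon gamma, heat shock, neutrophil granule, T cell and glycolysis genes in the 35 summed samples (points) of each group, with mean and SD as bars. The heat shock score averages 7.05 in SE-High and 5.84 in SE-Std, and the interferon gamma score 4.89 and 5.50.

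In uninfected pigs, where glucose was compared without bacteria, 0 genes passed by edgeR over libraries and 0 summed. At a nominal p below 0.05 there were 135 and 94 genes, where 471 would be expected. The smallest p-values belonged to TGM3, a transglutaminase (-3.00 over libraries and -3.20 summed), the potassium channel gene KCNN3 (-2.04 and -1.91), MMP8 (-2.64 and -2.82) and AGTPBP1 (-2.44 and -2.58). DESeq2 called 1 gene, TGM3, voom 1, KCNN3, and a fit of the control groups alone 8. The composition covariates gave 4, and without CON-Std replicate 4 TGM3 alone passed. Camera called 9 lists over libraries and 8 summed, with medians over libraries and summed such as -0.68 and -0.72 for mitochondrially encoded oxidative phosphorylation, -0.58 and -0.69 for erythroid and -0.48 and -0.40 for type I interferon genes. Complement and coagulation genes passed over libraries (0.48) but not summed (0.31). Camera with an estimated correlation and fry called 0, with adjusted p of at least 0.858. Groups of 3 samples allow an exact permutation p of 0.1 at best, so single scores could not pass.

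The interaction asked whether infection changed expression by a different amount at high than at standard glucose. By edgeR 0 genes passed over libraries and 0 summed, with 297 and 172 at a nominal p below 0.05, where 471 would be expected. DESeq2 gave 0, voom 7, surrogate variables 1 and the composition covariates 6. The smallest p-values belonged to ADGRB1, for which no fold is given because all CON-High libraries were at 0, KCNN3 (2.07 and 2.02), the oxygen sensor EGLN3 (-1.58 and -1.52) and DRAM1 (-2.79 and -2.73). Camera called 11 lists over libraries and 8 summed. Camera with an estimated correlation and fry called 0, with adjusted p of at least 0.621 and 0.657.

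Whether glucose moved genes along or against the infection response was read from the correlation of the glucose effect in infected pigs with the mean infection effect. It was -0.150 over libraries and -0.156 summed across 9428 genes. With the glucose labels shuffled over the infected samples, 29 and 32 of 100 arrangements, the real labels included, gave a correlation at least as far from 0. The median of the shuffled arrangements was not 0 but 0.0267 over libraries and 0.0554 summed, and distance from these medians was not counted.

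**Figure D5:**
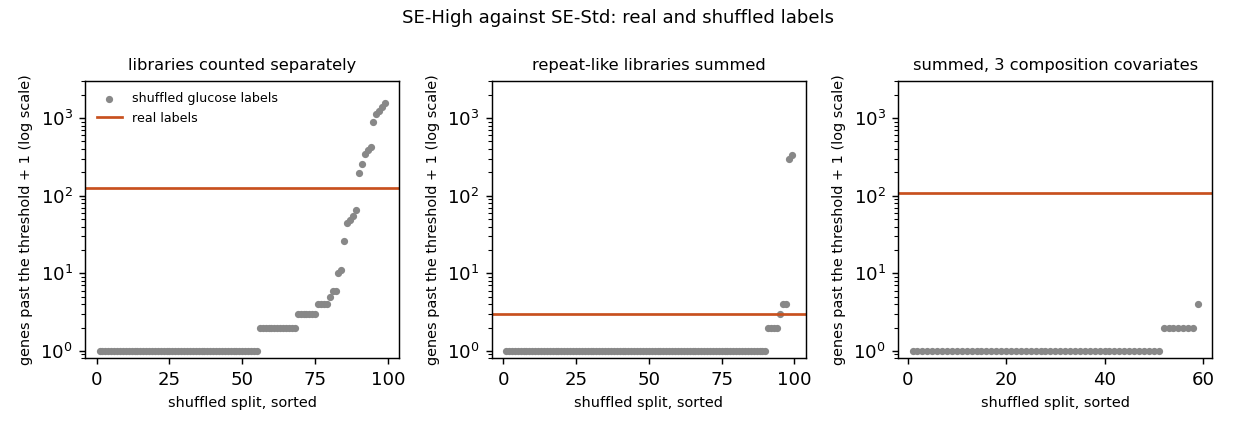
Genes past the threshold plus 1 (y axis, log scale) for SE-High against SE-Std in each shuffled arrangement of the infected samples (x axis, sorted by count), with libraries counted separately, libraries summed, and summed with 3 composition covariates, and the real labels as a line. The real labels give 124, 2 and 108 genes, and the highest shuffled counts are 1542, 333 and 3.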

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

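The tests of sample handling, of cell composition and of a weaker infection response, and the shuffles of the summed samples with composition covariates, were chosen only after the result was seen. The other shuffles and tests were fixed before their results were seen.

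The number of genes that differed with glucose in infected pigs went from 124 over libraries to 2 summed and 108 summed with composition covariates. Counting repeats separately is a candidate explanation for the first number, since 11 of 100 splits that kept the sets together but counted every library gave at least 124 genes, and the highest other split gave 1542. Splits that call this many genes point to a structure of the samples that the groups do not explain. With the covariates 1 of 60 splits, the real one, reached 108, and the highest other split gave 3. At a nominal p below 0.05 the real labels gave 1154 genes and the highest other split 1127. This fit was chosen after the data were seen, which the splits do not allow for, so chance was not excluded there. All 108 genes had the same sign without the covariates, in a fit of the same samples. What the covariates removed, cell composition or another difference between samples, was not tested further.

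Heat shock genes were higher at high glucose in infected pigs, with a score difference of 1.21 ± 0.28 (standard error) over 6 genes, 12 of 12 SE-High samples above the SE-Std mean and a permutation p of 0.00044. These genes were picked out of a list of 18 after their values were seen, and the score of the whole list did not pass (difference 0.411, permutation p = 0.0119, adjusted p = 0.185). Sample handling that also switches on immediate early genes would raise both kinds of gene. The median log2 fold change of the 12 other genes of the list, here called immediate early, was -0.026 (SD 0.26). For the heat shock genes it was 1.03. Because the 6 genes were set apart after their values were seen, part of this gap comes from the choice, so it cannot decide about handling. The samples with low scaling factors, SE-High replicate 1 (0.325) and SE-Std replicate 13 (0.410), do not account for the heat shock difference. The heat shock median without them was 1.005, with a standard error of the score difference of 0.28. An effect of the glucose supply may underlie it as a hypothesis, while sample handling, and reads shared between near-identical HSP70 copies, stay open.

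Interferon genes were lower at high glucose in infected pigs, with a type I score difference of -0.77 (10 of 12 SE-High samples below the SE-Std mean, permutation adjusted p = 0.459) and an interferon gamma difference of -0.61 (11 of 12 samples, adjusted p = 0.148). Neither score passed. Cell composition as measured by erythroid, mature neutrophil and T cell scores is argued against for the type I list, as its difference was -0.747 ± 0.259 with these scores as covariates, but platelet markers, not among the covariates, were lower too (score difference -0.54, 9 of 12 samples, permutation adjusted p = 0.563), so a share of platelets that moved with it stays open. A weaker infection response overall cannot be told apart from a change of interferon genes alone, because the difference as a share of the infection effect was -29.1% for the interferon genes and -2.83% for 1236 other raised genes, and the gap of -26.3 percentage points had a jackknife standard error of 13.8. An effect of glucose, a milder or later infection in these pigs, and variation between animals may each contribute, and the time course was not tested.

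For 11 gene lists the infection effect differed between the glucose supplies by camera's test of the interaction, with the median difference given as high minus standard, over libraries and then summed. The infection effect was more positive at high glucose for erythroid markers (0.953 and 1.02), mitochondrially encoded (0.796 and 0.648) and nuclear (0.358 and 0.393) oxidative phosphorylation, cell cycle (0.370 and 0.461) and cytosolic ribosomal genes (0.351 and 0.576). It was more negative for platelet markers (-1.09 and -0.823), complement and coagulation (-0.868 and -0.680), glycolysis (-0.418 and -0.268), cholesterol synthesis (-0.384 and -0.487), interferon gamma (-0.320 and -0.281) and type I interferon genes (-0.311 and -0.239). For some lists the control groups differed more than the infected groups. The mitochondrially encoded score averaged 7.49 in CON-Std and 6.70 in CON-High (n = 3 each), but 7.16 in SE-Std and 7.06 in SE-High. The erythroid score averaged 8.60 and 7.83 in these controls, but 8.78 and 8.96 in the infected groups. The platelet and both interferon scores differed more between the infected groups. The camera adjusted p over libraries ran from 1.4e-08 for erythroid markers to 0.0415 for interferon gamma genes, and glycolysis (0.131), type I interferon (0.0664) and interferon gamma genes (0.0730) did not pass summed. With composition covariates the erythroid, both oxidative phosphorylation and the cytosolic ribosomal lists reversed, the ribosomal list with a camera adjusted p of 3.5e-05, and 6 lists passed in place of 11. The erythroid score is itself a covariate, so the reversal of that list carries no information. With an estimated correlation or by fry 0 of the 11 passed, with adjusted p of at least 0.621 and 0.657, and 8 of 100 splits called at least 11 lists, with 13 as the highest other, so chance could not be excluded.

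Other splits of the same samples were counted for each result. For glucose in infected pigs 2 of 100 splits of the libraries reached 124 genes (highest other 303), but these splits part the repeats. Summed, 6 of 100 reached 2 genes (highest other 333) and chance could not be excluded, and splits with such counts again point to a structure of the samples. For the lists 5 of 100 splits reached 13 (highest other 18), and chance could not be excluded.

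For infection at high glucose 1 of 100 splits, the real one, reached 1395 genes over libraries (highest other 714), with the repeats parted. Summed, 1 of 100, again the real one, reached 874. That share is under 0.05, but the highest other split gave 828, so chance is argued against only narrowly. For the lists 3 of 100 splits reached 17 (highest other 18), but these splits part the repeats, and no splits of the summed samples were run for lists. The high counts of other splits point to a structure of the samples. At standard glucose 1 of 100 reached 1091 genes (highest other 6), with the repeats parted. Summed, 1 of 100 reached 667 (highest other 20), which argues against chance. For the lists 2 of 100 reached 18 (highest other 19), again with the repeats parted. For genes shared by both infection comparisons in 1 direction, 1 of 100 reached 697 over libraries (highest other 0), with the repeats parted. Summed, 1 of 100 reached 432 (highest other 1), which argues against chance.

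In uninfected pigs the real count was 0 genes, which every split reaches (35 of 35, highest other 1), so the splits test nothing there. For the lists 7 of 35 splits reached 9 (highest other 11), and chance could not be excluded. The 10 splits of the summed samples are too few for a share under 0.05, with 0 genes for the real labels, 0 for the highest other and 10 of 10 splits as large. The interaction also had a real count of 0, which every split reaches by construction (100 of 100 over libraries and 100 of 100 summed, highest other 0 in both), so nothing about chance follows. For the correlation of the glucose effect with the infection effect 29 of 100 splits over libraries were as far from 0 as 0.150 (highest other 0.348) and 32 of 100 summed as far as 0.156 (highest other 0.367), and chance could not be excluded.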

How the results depend on the processing

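All alternatives run on the summed samples, the summing itself, the removal of the most abundant ID and the permutation of list scores were chosen after seeing the data, and the others before. Unless stated, the cause of a change was not tested. Counts of genes stayed within 1.5 times under RLE size factors, no filter, a stricter filter, removal of haemoglobin genes or of the most abundant ID, and thinning to the smallest library. They did so too, for summed samples, with EIF1AY as a covariate or without the samples of low scaling factor.

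For glucose in infected pigs the 124 genes became 278 by DESeq2 and 275 by voom. With only the groups of the comparison, a fit with fewer samples to estimate the spread, they became 60. They became 343 with 2 surrogate variables, 298 with 3 composition covariates and 2 summed, and leaving out a control library gave 101 to 115. For glucose in infected, repeats summed, the 2 genes became 1 with wider repeat sets, 35 by DESeq2, 18 by voom and 108 with composition covariates, and leaving out a sample gave 2 to 14. For infection at high glucose the 1395 genes became 2566 by voom and 874 summed (691 to 1370 leaving out a library), and for infection at high glucose, repeats summed, the 874 became 177 with wider sets, which leave 2 CON-High samples, 1343 by DESeq2 and 2508 by voom (239 to 852). For infection at standard glucose the 1091 became 2742 by voom and 667 summed (597 to 1070), and for infection at standard glucose, repeats summed, the 667 became 1588 by voom (260 to 637). For glucose in uninfected pigs the 0 became 1 by DESeq2, 1 by voom, 8 with only the groups of the comparison and 4 with composition covariates (0 to 1), and summed 1 with composition covariates (0 to 0). For the interaction the 0 became 7 by voom, 1 with surrogate variables and 6 with composition covariates (0 to 0), and summed 1 with composition covariates. The correlation of the infection responses stayed between 0.739 and 0.784, and that of glucose with infection between -0.199 and -0.139.

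The lists past camera for glucose in infected pigs (13) became 1 with an estimated correlation, 3 by fry, and summed 0 with an estimated correlation, 0 by fry and 0 by list scores. For infection at high glucose (17) they became 1 with an estimated correlation, 11 with composition covariates and 0 summed with an estimated correlation. At standard glucose (18) they became 5 and, summed, 4 with an estimated correlation. For glucose in uninfected pigs (9) they became 0 with an estimated correlation and 0 by fry, and summed 0, 0 and, by list scores, 0. For the interaction (11) they became 0 with an estimated correlation, 0 by fry, 6 with composition covariates, and summed 0 and 0. Camera's preset correlation lies below the estimated correlation of each called list, which accounts for the calls lost by that change.

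With composition covariates 12 list calls reversed. These were nuclear oxidative phosphorylation for glucose in infected (camera adjusted p = 0.963), infection at high glucose (0.0549), glucose in uninfected (0.559) and the interaction (0.549). Neutrophil granule proteins (0.999) and mature neutrophil markers (0.999) reversed for glucose in infected. Erythroid markers reversed for infection at high glucose (0.645), glucose in uninfected (0.994) and the interaction (0.997), cytosolic ribosomal proteins for glucose in uninfected (0.000103) and the interaction (3.5e-05), and mitochondrial oxidative phosphorylation for the interaction (0.677). For erythroid and mature neutrophil markers the covariates are the lists' own scores.

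Single genes also reversed. With composition covariates ATP5PB stood at -0.029 and HADHA at -0.026 for infection at high glucose, HK2 at 0.067 and S100A8 at 0.22 for glucose in infected, PFKFB3 at 0.32 and CD14 at -1.03 for infection at high glucose, and CD14 at -1.22 for infection at standard glucose. By voom HK2 stood at 0.19 and S100A8 at 0.088 for glucose in infected, PFKFB3 at 0.063 and CD14 at -0.030 for infection at high glucose, and PFKFB3 at -0.023 for infection at standard glucose. With surrogate variables PFKFB3 stood at 0.25 and CD14 at -0.0090 for infection at high glucose, and CD14 at -0.081 for infection at standard glucose. PFKFB3 for infection at high glucose stood at 0.072 thinned to the smallest library, and between -0.23 and 0.096 without a control library (0.096 and 0.069 without CON-High replicates 2 and 4). PFKFB3 for infection at standard glucose stood at -0.068 with RLE size factors, -0.070 by DESeq2, -0.032 with no filter, -0.025 with only the groups of the comparison and -0.025 summed. Without a control library it stood between -0.098 and 0.062, at -0.0247 and -0.0246 without CON-High replicates 3 and 4 and at -0.098 without CON-Std replicate 2. After summing, 26 of the 47 named genes for glucose in infected no longer passed, against 14 of 97 for infection at high glucose and 16 of 95 for infection at standard glucose, where the totals include named genes that passed in neither fit. At 2360400 to 4294375 counts per library, genes with few control counts had ratios known only within wide intervals, which limits the size but not the direction of the largest rises.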

Other observations

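The comparisons of heat shock scores outside the infected pigs, of HBB shares and of the composition-adjusted lists were chosen only after the results were seen. In uninfected pigs the score of the 6 heat shock genes averaged 4.95 ± 0.58 log2 CPM (SD, n = 3) at high and 4.03 ± 0.22 (n = 3) at standard glucose, with 3 of 3 CON-High samples above all CON-Std samples and an exact permutation p of 0.1, the smallest that this design allows. With infection the score was higher by 2.10 at high glucose (exact permutation p = 0.00220, the smallest that these group sizes allow, with 12 of 12 samples above all controls) and by 1.81 at standard glucose (exact permutation p = 0.00263, with 17 of 17 samples above all controls). The score of the 12 immediate early genes did not differ with glucose in infected pigs (0.0097, permutation p = 0.939, 7 of 12 samples above the SE-Std mean).

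HBB held 4.41 ± 1.14% of the gene counts in infected samples (SD, n = 29) and 2.97 ± 0.40% in controls (n = 6), with a permutation adjusted p of 0.0303. The shares of the HTSeq categories that name no gene did not pass (adjusted p of at least 0.280).

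With composition covariates on the summed samples, 4 of 32 type I interferon genes were lower in SE-High (27 adjusted over the list alone) with a median of -0.80, 1 of 17 interferon gamma genes (12 alone) with -0.44 and 1 of 12 platelet markers (6 alone) with -0.64. Of 18 immediate early and heat shock genes 5 were higher (6 alone). Fry gave an adjusted p of 0.0472 for each of these 4 lists, and camera with an estimated correlation 0.235 for the type I interferon, interferon gamma and platelet lists and 0.260 for the heat shock list.

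EIF1AY was detected in 7 of 12 SE-High, 9 of 17 SE-Std, 1 of 3 CON-High and 2 of 3 CON-Std samples, so both sexes were present in every group. The first principal component of the summed samples carried 21.2% of the variance and the second 10.9%.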
